A study of Mus musculus with 27 samples.

How the data were processed

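Livers of male C57B/6J mice on 3 diets were profiled, with 3 mice per diet in each assay, per the labels. The diets differed in carbonyl iron: a standard-iron diet (SID, 50 mg per kg), a high-iron diet (HID, 8.3 g per kg) and a low-iron diet (LID, 0.9 mg per kg). HID and SID feeding began at 6 weeks of age and LID feeding at 3 weeks, per the labels, so low iron and an earlier start came together in every LID comparison. RNA was profiled in 9 libraries and DNA methylation in 18 libraries, an HpaII and an MspI library for each of 9 animals. HpaII cuts its site only when it is unmethylated and MspI cuts it either way. The labels do not say whether RNA and DNA came from the same animals.

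Reads were processed with TopHat and Cufflinks 2.2.1 on genome build mm9, per the submitters' processing notes. The deposited RNA table gave 1 FPKM value per gene and diet (fragment counts scaled to transcript length and library size), combined by the authors over the libraries of a diet. The unit was taken from the tool and the values, because the file headers do not name it. There were no values per library, so FPKM are printed without SD or n. The columns of the table were named NORM, LFE and GFE per the file headers. GFE was taken as HID by elimination, since its letter is not explained there. The deposited table also held the authors' p-value and adjusted p-value for each of the 3 contrasts. Those adjusted values equalled a Benjamini-Hochberg adjustment over all 3 contrasts together (34481 tests, largest gap 2.69e-06). The test behind the p-values is not given in the sources used here.

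The deposited methylation table held 1 score per locus and animal between 0 and 100 for 48 loci in 10 iron-related genes, per the file headers. How the score was made from the HpaII and MspI libraries, and its coverage, are not given in the sources used here, so depth is unknown. The header does not say whether a high score stands for more or less methylation. Loci in first exons and promoters (8) had a median SID score of 7.01 and the other 40 loci 35.3. Each locus had a deposited p-value, which equalled that of an F test across the 3 diets recomputed from the 9 scores (largest gap 4.80e-09). All 48 p-values were below 0.05 (highest 0.0494), so these loci had been selected for differing between the diets. Coordinates are those of the deposited table on mm9, and region names are the authors'.

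The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The planned limma and camera tests on RNA needed values per library and could not be fitted to 1 value per diet. In their place, a gene was called when the authors' adjusted p was below 0.05. Genes were tested with a mean of at least 1 FPKM over the 3 diets and a deposited adjusted p below 1. Changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The median change of tested genes was −0.07 for HID against SID, −0.13 for LID against SID and 0.06 for HID against LID, and log2 changes are printed relative to it.

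Each of 37 gene lists (789 genes, of which 767 were in the table) was tested when at least 4 members were tested. A one-sided Fisher's exact test compared called members with the other tested genes in each direction, with Benjamini-Hochberg adjustment over lists and directions within a contrast. Genes are not independent replicates, so these p-values describe the calls of these libraries. Calls adjusted over the list alone are given beside some counts. As an added alternative, cameraPR ranked genes by signed p with an inter-gene correlation preset at 0.01. No correlation could be estimated from 1 value per diet, so no list call was checked with an estimated correlation. Both the use of the Fisher test and the tested-gene rule were chosen after seeing the form of the table.

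Methylation scores were compared with limma over all 9 animals, with Benjamini-Hochberg adjustment over the 48 loci of a contrast. Exact two-sided permutation p-values stand beside some loci, and 3 animals against 3 cannot go below 0.1. Methylation differences were set against expression changes over 10 genes with 100000 permutations.

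The rule named, per contrast, the 10 called genes with the largest change in each direction, a fixed set of iron genes, up to 4 called members of each list (or 2 with the smallest p where none was called), and the 5 loci with the largest difference in each direction with all loci of fixed iron genes. Its further condition, that animals of the 2 diets do not overlap, could not be applied to RNA. Genes named outside it were Xist, Ddx3y, Alb, Hfe2 and Nr1d1 in all contrasts, with Prap1 and Slc11a2 in those where the rule did not name them, and they were chosen after their values were seen. Some genes that the rule named are not reported here.

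Alternatives fixed beforehand were other pseudocounts, filters and scalings, a replicate block, gene averages, a logit scale and leaving out each animal. Alternatives added after seeing the data were adjustment within a contrast, a 2-fold limit, cameraPR, other sets of tested genes for the lists, fits of only the 6 animals compared and fits within 1 code letter of the animals.

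On simulated data, a planted list with 8 of 20 members called was found in 100 of 100 runs for HID against SID (9473 genes), with 0.04 other lists past the threshold on average. For LID against SID, 8.28 of 12 simulated loci changed by 25 score units were found on average, with 0.32 unchanged loci called. In a further simulation, 48 unchanged loci were selected by the F test in the same way as the deposited ones. Calls averaged 24 for LID against SID, 23.4 for HID against SID (highest 34 in each) and 23.48 for HID against LID (highest 33). These loci varied independently of each other, so the ranges may be too narrow for loci that vary together within an animal.

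Of 22552 genes in the RNA table, 11374 had the status OK in the authors' deposited table, the same genes that had a deposited adjusted p below 1 in HID against SID. In that table, 25 gene names had been turned into dates; these genes stayed in the counts and are not named. Alb was listed at 0 in all 3 diets, Trf at 0 in LID, Cyp2b13 at 0 in SID and Prap1 at 0 in HID and LID, so no fold is given against those values, and without read counts a listed 0 cannot be read as no expression. Near-identical genes (Mup, Cyp2c, Cyp4a12, Hbb and Saa members, Hamp with Hamp2) may share reads, and their separate values are uncertain. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.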

Results

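Liver RNA and liver DNA methylation were measured in male C57B/6J mice on a standard-iron diet (SID), a high-iron diet (HID) or a low-iron diet (LID), with 3 mice per diet in each assay. RNA levels are the authors' combined FPKM, 1 value per gene and diet with no values per library, so they carry no SD. The listed FPKM summed to 467304 in SID, 485504 in HID and 420623 in LID, and the 10 highest genes took 17.8%, 18.1% and 20.6% of these sums. Alb in all diets and Trf in LID added nothing to the sums, so the sums do not cover the same genes in each diet. Read depth is unknown for both assays. Methylation scores are given as mean ± SD over 3 animals.

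The high-iron diet was compared with the standard diet to see which liver genes respond to iron loading. Genes that answer to iron through bone morphogenetic protein (BMP) signalling rose in HID. Hamp2, a close relative of the iron hormone gene Hamp, went from 275 to 2660 FPKM, and Id1, a direct BMP target, from 8.54 to 73.6 FPKM. The inhibitory SMAD gene Smad7 rose from 1.66 to 6.93 FPKM, Atoh8 from 7.45 to 23.3 and Bmp6, the ligand that signals liver iron, from 0.803 to 2.51. Genes that male mouse livers express more than female ones fell, among them Elovl3 (207 to 3.72 FPKM) and Hsd3b5 (136 to 3.64). Interferon-stimulated genes rose, with Rsad2 at 34.9 against 1.39 FPKM and Oasl1 at 33.6 against 3.16.

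At an adjusted p below 0.05 in the authors' deposited table, 631 of 9473 tested genes were called in HID against SID, 267 higher and 364 lower. Of the 19 tested members of the hepcidin and BMP-SMAD list, 7 rose and 0 fell (Fisher's exact adjusted p = 6.9e-06, with 10 higher when adjusted over the list alone). Their median log2 change was 0.59 relative to all tested genes. Smad6, another inhibitory SMAD, rose from 2.06 to 3.90 FPKM and Bmp2 from 3.73 to 7.10 FPKM. Hamp itself stood at 6028 FPKM in HID and 3200 in SID, with an adjusted p of 0.0685 in the authors' deposited table, and was not called. Hfe2, which encodes the BMP coreceptor hemojuvelin, stood at 39.1 against 31.5 FPKM and was not called.

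Among iron transport and storage genes, Tfrc, the transferrin receptor whose mRNA is kept stable when iron is scarce, fell from 4.56 to 1.85 FPKM. Slc40a1, the iron exporter ferroportin, rose from 35.9 to 79.95 FPKM, and Slc11a2, the iron importer DMT1, fell from 5.55 to 2.15. Lcn2, a siderophore-binding protein, rose from 4.76 to 18.6 FPKM. The ferritin subunit genes were not called, with Ftl1 at 4847 against 2892 FPKM and Fth1 at 1504 against 2122. Trf (2762 against 4825 FPKM) and Hmox1 (14.2 against 9.10 FPKM) were not called either. Over the whole iron handling list, 2 of 24 members rose and 3 fell, which was not past the threshold (Fisher's exact adjusted p = 0.404 higher and 0.241 lower). The haem list had 0 of 15 members called.

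The male-biased list fell as a block, with 16 of 16 tested members lower (Fisher's exact adjusted p = 1.15e-21) and a median log2 change of −2.24. Mup21 went from 1969 to 81.3 FPKM, Cyp4a12a from 97.6 to 5.35, and the complement gene C6 from 52.9 to 3.57. In the female-biased list 11 of 14 members rose and 0 fell (Fisher's exact adjusted p = 5.73e-14, median log2 change 1.62). Cyp2b9 rose from 0.443 to 150 FPKM and Cyp2a4 from 1.26 to 91.7, while Cyp2b13 stood at 16.2 FPKM and was listed at 0 in SID. The authors' call of Cyp2b13 is counted in this list and in the xenobiotic list, although a listed 0 can stand for a missing value. Of the 28 tested xenobiotic cytochrome P450 and regulator genes, 9 rose and 3 fell (Fisher's exact adjusted p = 7.42e-07 higher), and 4 of those 9 also belong to the female-biased list. Cyp2b10, a classical target of the receptor CAR, rose from 0.208 to 33.5 FPKM. In the growth hormone axis list, Igfals (30.04 to 14.6 FPKM) and Bcl6 (5.22 to 3.17 FPKM) fell among 13 members (Fisher's exact adjusted p = 0.303, cameraPR adjusted p = 0.00361 lower).

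Interferon-response genes gave the largest count of higher calls among the lists, 15 of 22 with 0 lower (Fisher's exact adjusted p = 1.91e-17), with Ifit1 at 31.9 against 3.28 FPKM and Isg15 at 45.1 against 9.32. Of 22 macrophage and Kupffer cell markers, 5 rose and 0 fell (Fisher's exact adjusted p = 0.00237), with Lyz2 at 63.3 against 30.4 FPKM, Vsig4 at 22.7 against 11.4 and Spp1 at 49.0 against 25.1. All 3 tested neutrophil markers were called higher, which was too few for a list test, with S100a8 at 9.15 against 2.38 FPKM. Hepatocyte identity genes had 0 of 21 members called, with a median log2 change of −0.17 (cameraPR adjusted p = 0.445 lower).

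Heat-shock genes fell, 6 of 12 with 0 higher (Fisher's exact adjusted p = 2.74e-05), with Hspb1 at 4.49 against 31.1 FPKM and Hspa1b at 4.24 against 17.6. In the oxidative-stress list of NRF2 targets and metallothioneins, 6 of 23 members rose and 2 fell (Fisher's exact adjusted p = 0.000319 higher). The metallothionein genes Mt1 (18.3 to 184 FPKM) and Mt2 (4.22 to 89.0) moved most, followed by the aldo-keto reductase Akr1b8 (1.49 to 8.27) and the glutathione transferase Gsta1 (2.195 to 8.71). Bile acid genes fell in 4 of 20 cases and rose in 2 (Fisher's exact adjusted p = 0.0446 lower). Cyp7b1 went from 57.8 to 10.9 FPKM, the uptake carrier Slco1a1 from 156 to 12.5 and Slco1a4 from 7.65 to 37.6, and 2 of the 4 that fell are also on the male-biased list. The fatty acid oxidation list had 4 of 29 members higher and 3 lower (Fisher's exact adjusted p = 0.0491 higher) although its median log2 change was −0.04, and the call was lost without the filter on low values and with adjustment within the contrast. Clock genes went both ways, 3 of 15 higher and 5 lower (Fisher's exact adjusted p = 0.0491 and 0.00156), with Dbp at 19.03 against 2.10 FPKM and Nfil3 at 3.66 against 17.3. The bile acid, fatty acid oxidation and clock lists did not pass with cameraPR (adjusted p = 0.436, 0.936 and 0.682).

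Some large single changes fell outside the lists that passed. Mup5, which is on none of the lists, went from 1035 to 0.342 FPKM. Ccnd1, the cyclin D1 gene, rose from 4.16 to 38.9 FPKM while 7 of 8 cell cycle members were not called. In the ER stress list, Creld2 (47.6 to 12.5 FPKM), Sdf2l1 (33.8 to 8.96) and Herpud1 (180 to 87.3) fell. This list was not past the threshold with Fisher's exact test (adjusted p = 0.155 lower) but was with cameraPR (adjusted p = 8.8e-06 lower), and 7 of its 19 members were lower when adjusted over the list alone. Alas2, the erythroid haem synthesis gene, fell from 44.0 to 8.71 FPKM.

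**Figure D1:**
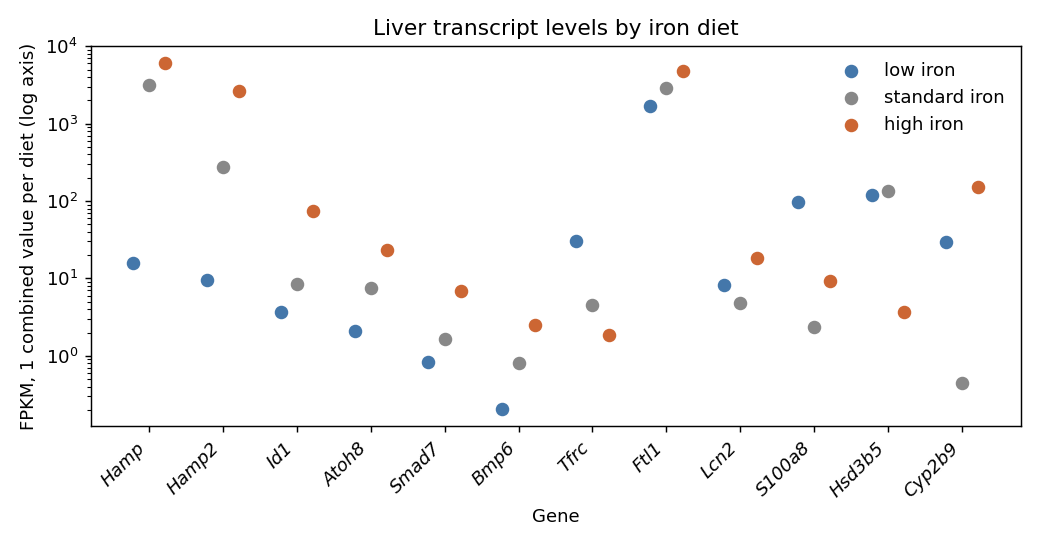
Authors' combined FPKM of 12 genes on a log axis, with 1 point per diet (blue LID, grey SID, orange HID) and no error bars because there are no values per library. Hamp, Hamp2, Id1, Atoh8, Smad7 and Bmp6 stand in the order LID, SID, HID, and Tfrc in the opposite order, at 30.4, 4.56 and 1.85 FPKM.

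The low-iron diet was compared with the standard diet to see which genes respond to iron shortage. Hepcidin transcripts fell steeply in LID livers: Hamp went from 3200 to 15.8 FPKM and Hamp2 from 275 to 9.42. Tfrc rose from 4.56 to 30.4 FPKM. Neutrophil genes rose, with S100a8 at 96.7 against 2.38 FPKM and S100a9 at 82.7 against 3.80.

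At an adjusted p below 0.05 in the authors' deposited table, 463 of 9482 genes were called in LID against SID, 149 higher and 314 lower. This imbalance depended on the cut, with 68 higher and 63 lower at a 2-fold limit. Of 19 hepcidin and BMP-SMAD genes, 6 fell and 0 rose (Fisher's exact adjusted p = 0.000244, with 10 lower when adjusted over the list alone). Besides Hamp and Hamp2 these included the BMP targets Id1 (8.54 to 3.65 FPKM), Id2 (101 to 35.2), Id3 (52.0 to 8.90) and Atoh8 (7.45 to 2.08). Bmp6 stood at 0.205 against 0.803 FPKM, Smad7 at 0.841 against 1.66 and Smad6 at 1.32 against 2.06, and none of the 3 was called. In the iron handling list Tfrc was the only 1 of 23 members called. Ftl1 (1713 against 2892 FPKM), Fth1 (1694 against 2122), Slc40a1 (29.2 against 35.9), Hmox1 (13.6 against 9.10) and Lcn2 (8.33 against 4.76) were not called. Trf was listed at 0 in LID and was not tested. In the haem list, Alas1 (95.5 to 59.2 FPKM) and Abcb6 (16.2 to 9.54) fell among 15 members (Fisher's exact adjusted p = 0.222).

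Blood-cell genes changed. In the neutrophil list 6 of 7 members rose (Fisher's exact adjusted p = 2.26e-09), with Camp at 5.39 against 0.0540 FPKM and Retnlg at 5.64 against 0.251. Of the 6, 4 stood under 0.5 FPKM in HID and SID, were not tested in HID against SID and passed the filter through their LID values, and with genes tested in all 3 contrasts 3 members were left, too few for a list test. With all genes in the table as background and untested genes taken as not called, 8 of 14 members rose (Fisher's exact adjusted p = 1.31e-12). Ppbp, a platelet chemokine gene, rose from 0.213 to 8.18 FPKM. In the erythroid list 3 of 9 rose and 1 fell (Fisher's exact adjusted p = 0.00245 higher). Hbb-b1 (177 to 408 FPKM) and Car2 (1.98 to 5.19) were among those that rose, and Alas2 (44.0 to 27.4) fell. Of 22 macrophage and Kupffer markers 9 rose and 0 fell (Fisher's exact adjusted p = 6.9e-10), with Marco at 11.4 against 3.68 FPKM and Spic, a regulator of iron-recycling macrophages, at 1.92 against 0.577. Of 6 MHC class II genes 3 fell (Fisher's exact adjusted p = 0.00401), with Cd74 at 25.5 against 43.8 FPKM. Interferon genes rose in 5 of 22 cases (Fisher's exact adjusted p = 0.000228), with Isg15 at 17.1 against 9.32 FPKM. Markers of other tissues, mostly pancreatic enzymes, had 0 of 7 members called but a median log2 change of 0.68 (cameraPR adjusted p = 0.0139 higher), with Cela2a at 4.07 against 2.06 FPKM and Pnlip at 2.12 against 0.999.

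Hypoxia-response genes rose in 3 of 20 cases and fell in 1 (Fisher's exact adjusted p = 0.0171 higher). Ankrd37 (0.834 to 11.5 FPKM) and Ndrg1 (4.997 to 8.74) were among those that rose, and Bhlhe40 (20.7 to 11.8) fell. Among genes tested in all 3 contrasts this call was lost (adjusted p = 0.108). Cholesterol synthesis genes rose in 3 of 23 cases (Fisher's exact adjusted p = 0.0241), with Idi1 at 144 against 74.8 FPKM. Fatty acid synthesis genes rose in 3 of 20 cases (Fisher's exact adjusted p = 0.0171), with Acss2 at 185 against 94.2 FPKM and Gpam at 33.2 against 17.2. In the fatty acid oxidation list 4 of 29 rose and 2 fell (Fisher's exact adjusted p = 0.00567 higher, median log2 change −0.17), with Pdk4 at 12.4 against 4.50 FPKM and Cyp4a14 at 290 against 136. Bile acid genes fell in 5 of 20 cases and rose in 1 (Fisher's exact adjusted p = 0.00269 lower), with Cyp8b1 at 100.03 against 200.4 FPKM. Of the 5 that fell, 1 is also on the male-biased list. In the oxidative-stress list 4 of 23 rose and 2 fell (Fisher's exact adjusted p = 0.00269 higher), and Mt1 (18.3 to 109 FPKM) and Mt2 (4.22 to 52.6) rose here as they did in HID.

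Protein-folding genes fell in LID. The heat-shock list had 6 of 12 members lower (Fisher's exact adjusted p = 1.41e-05), with Hspa1b at 3.15 against 17.6 FPKM and Hsph1 at 10.5 against 28.2. The ER stress list had 5 of 19 lower and 0 higher (Fisher's exact adjusted p = 0.00245), with Creld2 at 16.3 against 47.6 FPKM and Herpud1 at 76.8 against 180. Male-biased genes fell in 9 of 16 cases (Fisher's exact adjusted p = 7.18e-09), with Cyp2d9 at 248 against 698 FPKM and Selenbp2 at 26.7 against 85.6. Female-biased genes rose in 9 of 13 cases (Fisher's exact adjusted p = 2.24e-12), with Cyp2c40 at 265 against 21.6 FPKM and Cyp2b9 at 29.1 against 0.443. The xenobiotic list had 3 of 26 higher and 3 lower (Fisher's exact adjusted p = 0.0321 higher), and 2 of the 3 higher genes are also on the female-biased list. Clock genes fell in 3 of 15 cases and rose in 1 (Fisher's exact adjusted p = 0.0487 lower), with Tef at 3.37 against 8.10 FPKM, and this call was lost among genes tested in all 3 contrasts (adjusted p = 0.0531). Hepatocyte identity genes had 0 of 20 members called, with a median log2 change of −0.22 (cameraPR adjusted p = 0.280 lower). With cameraPR 5 of the lists that passed in LID were lost: erythroid (adjusted p = 0.174), oxidative stress (0.540), fatty acid oxidation (0.375), bile acid (0.174) and xenobiotic (0.352).

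**Figure D2:**
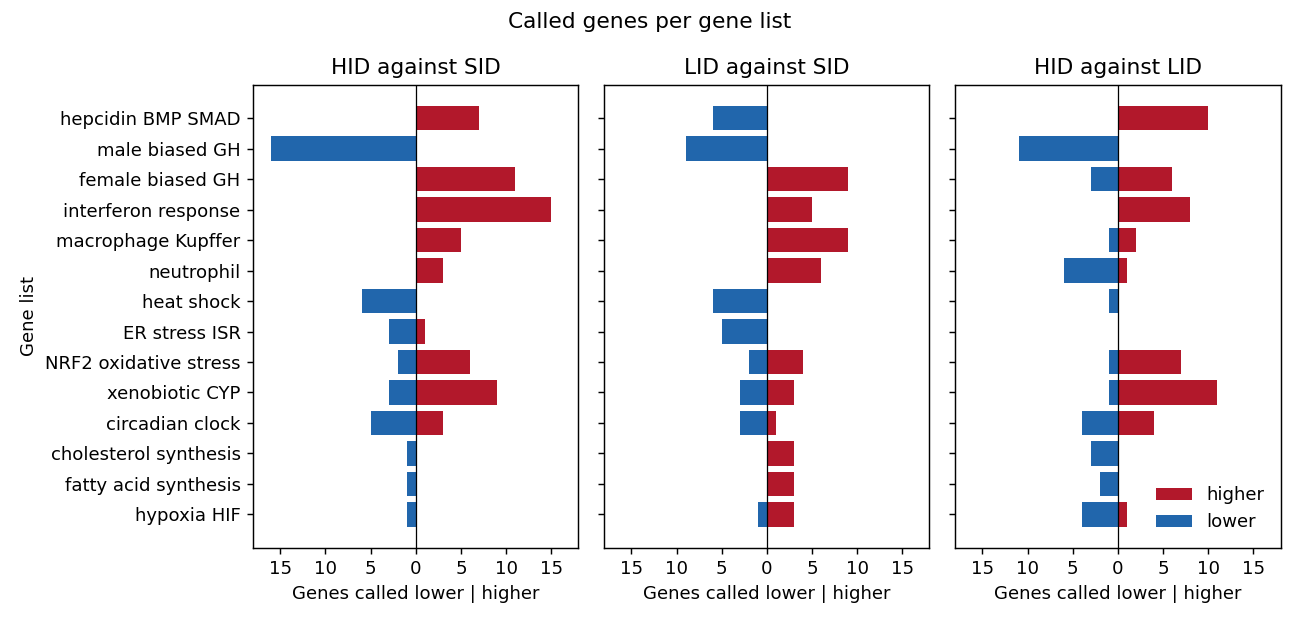
Number of genes called higher (red, to the right of 0) and lower (blue, to the left) in 14 gene lists for HID against SID, LID against SID and HID against LID. Of hepcidin BMP SMAD genes, 7 were higher in HID than SID, 6 lower in LID than SID and 10 higher in HID than LID. Heat shock genes were lower than SID in both diets, 6 each, and 1 was lower in HID than LID.

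HID and LID were also compared directly, which spans the full range of dietary iron. Genes of the hepcidin pathway were far higher in HID: Hamp stood at 6028 FPKM in HID and 15.8 in LID, Hamp2 at 2660 and 9.42, and Id1 at 73.6 and 3.65. Tfrc was lower in HID, at 1.85 against 30.4 FPKM. Ftl1 was higher in HID, at 4847 against 1713 FPKM, as were Slc40a1 (79.95 against 29.2) and Lcn2 (18.6 against 8.33). At an adjusted p below 0.05 in the authors' deposited table, 374 of 9490 genes were called, 199 higher and 175 lower in HID. The iron handling list had 3 of 23 members higher and 2 lower, and the erythroid list 2 of 9 lower, neither past the threshold (Fisher's exact adjusted p = 0.0531 higher and 0.0531 lower). Both passed without the filter on low values and with adjustment within the contrast, and with cameraPR the erythroid list passed (adjusted p = 0.0137) and the iron handling list did not (0.0581). Among genes tested in all 3 contrasts neither passed (Fisher's exact adjusted p = 0.0579 and 0.358), with 1 of 8 erythroid members lower. With all genes in the table as background both passed (Fisher's exact adjusted p = 0.0112 for iron handling and 0.00335 for erythroid).

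Of 19 hepcidin and BMP-SMAD genes, 10 were higher in HID and 0 lower (Fisher's exact adjusted p = 3.7e-11). These included Bmp6 (2.51 against 0.205 FPKM), Bmp2 (7.10 against 2.30), Smad6 (3.90 against 1.32), Smad7 (6.93 against 0.841) and Atoh8 (23.3 against 2.08). Interferon genes were higher in HID in 8 of 22 cases (Fisher's exact adjusted p = 1.16e-07), with Rsad2 at 34.9 against 2.18 FPKM. Neutrophil genes were lower in HID in 6 of 7 cases (Fisher's exact adjusted p = 4.48e-09), with S100a8 at 9.15 against 96.7 FPKM, and Lcn2 was the 1 higher. Here too 4 of the 6 passed the filter through their LID values, and with all genes in the table as background 8 of 14 were lower (Fisher's exact adjusted p = 2.72e-12). The markers of other tissues had a median log2 change of −0.98 in HID against LID, with 0 of 7 called (cameraPR adjusted p = 0.000388 lower). Hypoxia genes were lower in HID in 4 of 20 cases and higher in 1 (Fisher's exact adjusted p = 0.00309 lower), with Ankrd37 at 0.861 against 11.5 FPKM. Oxidative-stress genes were higher in 7 of 23 cases and lower in 1 (Fisher's exact adjusted p = 3.04e-06 higher), with Gsta2 at 22.8 against 4.58 FPKM. Cholesterol synthesis genes were lower in 3 of 23 cases (Fisher's exact adjusted p = 0.0428), with Mvd at 8.64 against 18.01 FPKM. Heat-shock genes were lower in HID in 1 of 12 cases and higher in 0 (Fisher's exact adjusted p = 0.481 lower). The ER stress list had 0 of 19 members called. Against SID, the same 6 heat-shock genes were lower in both diets. Both diets were set against the same SID values, so SID out of place could also give such falls, which was not tested.

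Sex-biased genes differed between HID and LID as well. Male-biased genes were lower in HID in 11 of 18 cases (Fisher's exact adjusted p = 1.25e-13), with Hsd3b5 at 3.64 against 119 FPKM and Elovl3 at 3.72 against 111. Female-biased genes were higher in 6 of 14 cases and lower in 3 (Fisher's exact adjusted p = 2.47e-06 and 0.0126). Cyp2b9 (150 against 29.1 FPKM) and Cyp2b13 (16.2 against 0.217) were higher, and Cyp2c69 (6.32 against 93.4) and Cyp2c40 (44.5 against 265) were lower. Xenobiotic genes were higher in 11 of 28 cases and lower in 1 (Fisher's exact adjusted p = 9.87e-11 higher), with Cyp2b10 at 33.5 against 0.142 FPKM. Of those 11, 4 also belong to the female-biased list. Bile acid genes were higher in 3 of 20 cases and lower in 2 (Fisher's exact adjusted p = 0.0428 higher), with Abcc3 at 26.5 against 6.86 FPKM, and this call was lost with adjustment within the contrast. Both bile acid genes that were lower are also on the male-biased list. The perinatal list had 2 of 5 lower, Tff3 (8.97 against 40.4 FPKM) and Cd24a (3.14 against 7.63), and Gpc3 higher (Fisher's exact adjusted p = 0.0196 lower), and this call was lost without the filter on low values. Clock genes were higher in 4 of 15 cases and lower in 4 (Fisher's exact adjusted p = 0.00171 and 0.00117), with Dbp at 19.03 against 0.675 FPKM. The oxidative-stress, bile acid, perinatal and clock lists did not pass with cameraPR (adjusted p = 0.137, 0.436, 0.911 and 0.358).

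Changes in the 2 iron diets, both taken against SID, were related across 9467 genes. Pearson's r was 0.52 and Spearman's rho 0.55 across genes, which are not independent replicates. Because both contrasts share the SID libraries, unchanged groups simulated against SID gave a mean correlation of 0.342 (highest 0.374) over 9462 genes. These were the genes also tested in HID against LID. The covariance of log2 changes was 0.1003 against a simulated 0.0140, a difference of 0.0863. In the calls, 61 genes were higher in both diets where independent lists give 3.97, and 102 were lower in both where they give 12.1. In opposite directions, 13 genes were higher in HID and lower in LID (8.79 from independent lists) and 4 were lower in HID and higher in LID (5.46). SID has 1 combined value and could not be split, so part of the excess may come from the shared controls.

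DNA methylation scores were available for 48 loci in Bmp2, Bmp6, Smad6, Smad7, Smad9, Ftl1, Slc11a2, Slc39a5, Slc39a11 and Steap3, genes of BMP signalling and of iron and zinc handling. LID livers differed from SID livers at most of these loci. At a Bmp6 exon 1 locus (mm9 chromosome 13, 38438105 to 38438108) the score was 45.6 ± 22.2 (SD, n = 3) in LID and 3.96 ± 2.76 (SD, n = 3) in SID. At a Smad6 exon 1 locus (chromosome 9, 63868025 to 63868028) it was 45.9 ± 19.95 in LID and 4.59 ± 1.997 in SID (SD, n = 3 each). At the Ftl1 intron 2 locus (chromosome 7, 52714382 to 52714385) it was 43.5 ± 19.4 in LID and 6.62 ± 4.14 in SID (SD, n = 3 each).

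With limma, 44 of 48 loci passed an adjusted p of 0.05 in LID against SID, 29 higher and 15 lower. The smallest adjusted p was 0.00503, and at 47 loci the 3 LID animals did not overlap the 3 SID animals. Each of those 47 had the smallest exact permutation p possible, 0.1. All 3 Bmp6 loci and 11 of 13 Smad6 loci had a higher mean in LID. Both Bmp2 loci, in exon 1, rose from a gene mean of 10.6 to 40.6. Smad7 was mixed, with an intron 1 locus (chromosome 18, 75530172 to 75530175) at 43.8 ± 18.2 against 5.83 ± 1.40 and an intron 3 locus (75551309 to 75551312) at 45.01 ± 11.03 against 70.3 ± 3.39 (SD, n = 3 each). Slc39a11, a zinc transporter gene, had 6 loci higher and 5 lower, and at its intron 7 locus (chromosome 11, 113116291 to 113116294) the score fell from 54.9 ± 7.70 in SID to 23.1 ± 10.5 in LID (SD, n = 3 each). The 48 loci had been selected by the F test, and simulated unchanged loci selected the same way gave a mean of 24 calls (highest 34). Animals did not overlap at 30.24 of these simulated loci on average and at 38 at most. The simulated loci varied independently, whereas real loci may vary together within an animal. Counts of 44 and 47 above these ranges therefore do not show a difference beyond selection. All SID animals carried a code of letter A and all LID animals one of letter M, so diet and code letter cannot be told apart here.

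**Figure D3:**
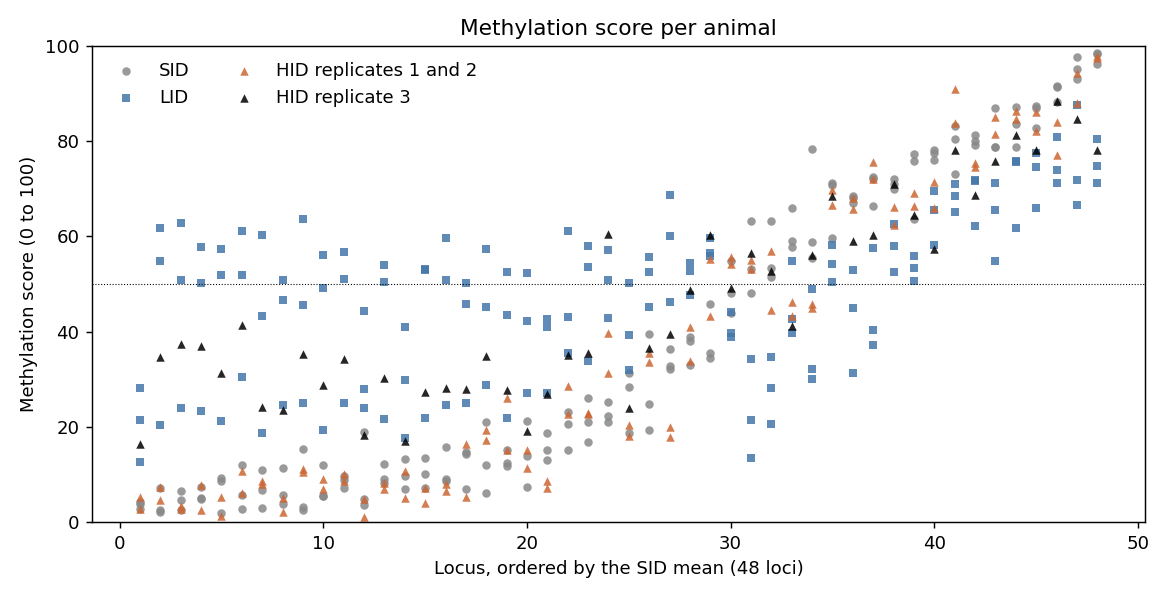
Methylation score (0 to 100) of each animal at the 48 loci, ordered by the SID mean, with grey circles for SID, blue squares for LID, orange triangles for HID replicates 1 and 2, black triangles for HID replicate 3 and a dotted line at 50. LID was higher at 29 of 30 loci with a SID mean under 50 and lower at 18 of 18 loci with a SID mean over 50. The SID mean also enters these differences, so their directions were partly set in advance.

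Few differences were found between HID and SID livers at these loci. With limma 0 of 48 loci passed the threshold in HID against SID, and 3 had an unadjusted p below 0.05. At 4 loci the animals did not overlap. Simulated unchanged loci selected by the F test gave means of 23.4 calls and 29.52 loci without overlap, but they varied independently. The 48 real loci were selected for differing across all 3 diets, so the count of 0 does not speak for other loci. The largest differences were at Slc39a11: intron 7 (chromosome 11, 113144890 to 113144893) at 43.9 ± 15.1 against 22.9 ± 2.196, and intron 5 (113323691 to 113323694) at 43.6 ± 2.60 against 60.9 ± 4.49 (SD, n = 3 each), both with a limma adjusted p of 0.307. The Bmp6 exon 1 locus stood at 15.5 ± 16.6 in HID (SD, n = 3), with 34.7 in HID replicate 3 and 4.62 and 7.31 in the others. Among animals of code letter A alone, 2 loci passed, both lower in HID, the Slc39a11 intron 5 locus and the Smad7 intron 3 locus at 75543378.

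In HID against LID, 33 loci passed with limma, 9 higher and 24 lower in HID. Unchanged loci selected by the F test gave a mean of 23.48 calls and a highest of 33, so the count was not above the range that selection alone gave. At 20 loci the animals did not overlap, fewer than the mean of 29.76 at such unchanged loci. The Smad7 intron 3 locus (chromosome 18, 75543378 to 75543381) was lowest relative to LID, at 25.7 ± 11.9 against 58.4 ± 11.3 (SD, n = 3 each, limma adjusted p = 0.0135). At the Slc39a11 intron 7 locus at 113116291 HID stood at 54.9 ± 1.68 and LID at 23.1 ± 10.5 (SD, n = 3 each, limma adjusted p = 0.013). The count depended on which animal was left out. It was 0 without HID replicate 1, 0 without HID replicate 2, 3 without LID replicate 2 and 4 without LID replicate 3. It was 38 without HID replicate 3 and 36 without LID replicate 1. The unadjusted limma p stayed below 0.05 at 24 loci without HID replicate 1 and at 23 without HID replicate 2. Fitted with only the 6 animals of these diets, 0 loci passed and 31 had an unadjusted limma p below 0.05.

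Methylation differences were set against expression changes over the 10 genes with both measurements. Pearson's r across genes was 0.432 for HID against SID, −0.385 for LID against SID and −0.270 for HID against LID, and Spearman's rho was 0.248, −0.539 and −0.248. Over these 6 relations every permutation p adjusted to 0.493, with raw values from 0.115 to 0.493. Without the 2 genes farthest from the median, r was 0.236, −0.0960 and −0.137. With the locus of largest difference in place of the gene mean, r was 0.423, −0.119 and −0.255 and rho 0.261, −0.515 and −0.527. Ftl1, Bmp6 and Smad6 all had higher gene mean scores in LID than in SID, and their transcripts stood lower in LID but were not called. In HID against LID their gene mean scores differed by −30.9, −23.7 and −17.8, and their transcripts were called higher. These 3 genes were picked out of 10 and the relation across all 10 did not pass.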

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

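Among the settings below, the 2-fold limit, adjustment within a contrast, cameraPR, the sets of tested genes for the lists, the fits of 6 animals and those within 1 code letter were chosen after seeing the data. Fewer genes were called among genes with a mean of at least 5 FPKM, 368 for HID against SID and 229 for HID against LID, because fewer genes were tested. A 2-fold limit left 232 (HID against SID, 116 higher), 131 (LID against SID, 68 higher) and 222 (HID against LID, 121 higher), by its construction. In LID against SID 51.9% of these were higher, against 32.2% of all called genes and 22.2% of those of at least 5 FPKM. No called gene turned its direction under another pseudocount, quantile normalization or median centring, which leave the authors' p-values untouched and so can only turn directions. Counts without a filter (735, 509 and 437) and with adjustment within a contrast (702, 463 and 338) stayed within 1.5 times. The perinatal list (HID against LID) was lost without a filter and the bile acid list (HID against LID) with adjustment within the contrast, and fatty acid oxidation (HID against SID) with either. Gained were erythroid and iron handling (HID against LID) with either, and immediate-early and sinusoidal endothelium (LID against SID) without a filter. Of the lists that passed, 8 of 11 (HID against SID), 13 of 18 (LID against SID) and 8 of 12 (HID against LID) also passed with cameraPR. The lists it lost, often with members called in both directions, were bile acid in all 3 contrasts, fatty acid oxidation against SID in both diets, clock in both HID contrasts, oxidative stress in both LID contrasts, erythroid and xenobiotic in LID against SID, and perinatal in HID against LID. Among genes tested in all 3 contrasts 11, 15 and 11 lists passed, without neutrophil (both LID contrasts, with 3 members left), clock and hypoxia (LID against SID). With all genes in the table as background 14, 23 and 19 passed. This setting added untested genes, taken as not called, and also genes below the filter, some of which were called. The share of each in the rise was not separated. For 333 named gene results, 1330 alternative values kept their side of the threshold and 2 were weaker (Serpina3n and Kdm3a, HID against LID). Direction was compared only for called genes. Only adjustment within a contrast could change the side, because the other settings counted here kept the authors' adjusted p-values. In the methylation fits, leaving out 1 animal at a time gave 0 loci throughout for HID against SID, 33 to 45 for LID against SID and 0 to 38 for HID against LID. The HID against LID count was 38 without HID replicate 3 and 36 without LID replicate 1. It fell to 0 without HID replicate 1 or HID replicate 2, to 3 without LID replicate 2 and to 4 without LID replicate 3. It was also 0 with only the 6 animals of the 2 groups and 0 with only animals of code letter M (1 HID and 3 LID animals), where fewer animals were fitted and the lone HID animal was assumed to vary like the others. Only animals of code letter A gave 2 loci for HID against SID, and the cause was not tested. Gene averages gave 7 genes (LID against SID) and 6 genes (HID against LID) of 10, because 10 genes and not 48 loci were tested. With a replicate block the counts were 0, 45 and 34 for HID against SID, LID against SID and HID against LID. Same-numbered animals correlated above 0.1 in only 4 of 9 pairs (−0.499 to 0.757), and the own number was best in 4 of 9, so the numbers do not pair animals. For 39 named locus results, 450 alternative values were the same, 79 weaker, 2 stronger and 2 moved. Not run for RNA, because each needs values per library, were leaving out libraries, the 2-group fit, the empirical Bayes options, fry, the estimated correlation and count tests. No paired analysis was possible for RNA because the columns carry no replicate number. Depth is unknown in both tables, so limits from counting error could not be given.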

Other observations

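The tests weighed here on methylation, sex-biased genes and clock genes were all chosen after the results were seen, and only the counts of other splits of the animals were planned. Genes of the growth-arrest and p53 list rose in LID with Cdkn1a at 15.9 against 6.49 FPKM in SID and Btg2 at 12.3 against 3.21, 2 of 13 members (Fisher's exact adjusted p = 0.0615, cameraPR adjusted p = 0.00387). In HID 0 of 13 were called, and cameraPR also put the list higher (adjusted p = 0.0337), with a median log2 change of 0.32 against 0.28 in LID. Btg2 is also on the list of immediate-early genes that respond to handling, where 2 of 13 members rose and 2 fell in LID (Fisher's exact adjusted p = 0.0615 higher and 0.186 lower), with Egr1 at 19.9 against 9.11 FPKM. That list passed without the filter on low values. Igfbp1, an insulin-repressed gene of the growth hormone axis list, rose from 105 to 226 FPKM in LID, and stood at 82.0 in HID. In the list of methyl-group and DNA methylation genes, Mat2a, which makes S-adenosylmethionine, rose from 16.9 to 31.0 FPKM in HID, where 1 of 18 members rose and 1 fell. In LID, Mbd3, which encodes a methyl-CpG-binding protein family member, fell from 24.7 to 14.97 FPKM, the 1 of 18 called. Of the iron-dependent dioxygenase list, 0 of 26 members were called in LID and 2 fell in HID, among them Plod1 (10.1 to 6.36 FPKM). For HID, Fisher's exact test of that list did not pass (adjusted p = 0.543 lower) and cameraPR did (adjusted p = 0.00789). The iron-sulphur and respiratory chain list had 0 of 30 members called in HID, and in LID Glrx5, an iron-sulphur cluster assembly gene, fell from 103 to 59.8 FPKM as the 1 called (Fisher's exact adjusted p = 1, cameraPR adjusted p = 0.0495).

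Stellate cell and matrix genes rose in 2 of 15 cases in each diet, Vim in both (13.9 in HID and 13.3 in LID against 7.92 FPKM), Lum in HID and Col4a1 in LID. The Fisher test passed in neither diet (adjusted p = 0.241 and 0.0772) and cameraPR in both (adjusted p = 0.00256 in HID and 3.72e-05 in LID). Sinusoidal endothelium markers rose in 3 of 18 cases in HID (Fisher's exact adjusted p = 0.066), with Lyve1 at 4.23 against 2.34 FPKM, and the other 2 were Bmp6 and Bmp2, also counted in the hepcidin and BMP-SMAD list. The acute-phase gene Apcs rose from 141 to 327 FPKM in HID and to 291 in LID, and Saa4 fell from 53.6 to 26.6 and 31.0. Prap1 was listed at 5.09 FPKM in SID and at 0 in both other diets, and as a listed 0 can stand for a missing value here, its calls in the authors' table are not read as a fall. Tff3, of the perinatal list, fell from 74.7 to 8.97 FPKM in HID and to 40.4 in LID.

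LID scores were higher at 29 of 30 loci with a SID mean under 50 and lower at 18 of 18 loci over it. The SID mean both divided the loci and entered the difference, and scores are bounded, so these directions were partly set in advance. HID replicate 3, the only HID animal with a code of letter M, lay between SID and LID: its median share of the LID minus SID difference was 0.527, against 0.0457 and −0.00552 in the A-coded HID replicates and 0.556, 1.31 and 1.17 in the LID animals. A low-iron diet as the only source would leave HID replicate 3 near SID, but the share of 0.527 in this 1 animal is part of the pattern and decides nothing, so this stays open. Separate handling of animals coded M stays open and undecided. HID replicate 3 departed from the other HID animals toward LID at 42 of 48 loci, but this restates the pattern and cannot test it, because no other diet has both letters. The letter's meaning is not given in the sources used here. The rules for these 2 tests were rewritten after their results were seen. A pull of every score toward 1 middle value stays open: with no margin 3 loci, all in Slc39a11, went against even the best middle value, and 1 locus did with a margin of the median LID SD (10.8), a margin set after the count without it was known, so the outcome rests on that choice. An effect of low iron or of the earlier diet start on methylation, beside any handling effect, also stays open, as untested.

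With 10 splits of 6 animals, no share under 0.05 can be reached. The loci had also been selected by the F test for differing between the real diets, which favours the real split in advance. The counts of loci per split therefore decide nothing. For LID against SID 1 of the 10 splits, the real one, gave 44 loci and the highest other split 0. For HID against LID 1 of 10, the real one, gave 33 loci and the highest other 24, from the split that put LID replicate 1 with HID replicates 1 and 2. For HID against SID all 10 splits gave 0 loci.

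Against SID, 16 of 16 male-biased genes were called lower in HID and 9 of 16 in LID, and 11 of 14 female-biased genes were called higher in HID and 9 of 13 in LID. In LID the male-biased Slco1a1 (167 against 156 FPKM) and Hsd3b5 (119 against 136) were not called. Female animals among the HID or LID libraries are argued against by Xist, which was at most 0.0110 FPKM in the 2 diets, while the Y-linked Ddx3y stood at 13.8 in both and 11.3 in SID. SID libraries alone out of place could not give the difference between HID and LID, where 11 of 18 male-biased genes were lower in HID, but could still contribute to LID against SID. A candidate explanation is an altered growth hormone signal with the diets, which was not tested. In the LID comparisons, low iron and the earlier diet start cannot be told apart for these genes either. Of the growth hormone axis list, 2 of 13 members fell in HID (Fisher's exact adjusted p = 0.303, cameraPR adjusted p = 0.00361), and in LID 1 rose and 1 fell.

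Clock genes differed between HID and SID in both directions. All 8 called genes of the clock arms moved with their arm, 100% (Nr1d2, Dbp and Usp2 higher, Arntl, Clock, Npas2, Nfil3 and Cry1 lower), so livers taken at different clock times may account for the difference. Nr1d1 stood at 17.9 against 12.1 FPKM and was not called. In HID against LID 8 of 8 called clock-arm genes moved with their arm, and in LID against SID 3 of 3. Clock time may therefore bear on those contrasts too, and on other genes whose levels change over the day. An effect of the diets on the clock itself cannot be told apart from different clock times, because 0 of 27 samples have a collection time in their labels.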
